A study of Mus musculus with 9 samples.

How the data were processed

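Per the labels, total RNA from spinal cord of B10.PL mice was hybridised to 1-colour arrays, 1 array for each of 9 samples: 3 naive, 3 with EAE given placebo and 3 with EAE given 200 ng of calcitriol, the last 6 taken 6 h after treatment. The labels give no batch or date. Replicate numbers run across the series and do not pair samples between groups. Nothing in the labels says whether replicates of a group are separate animals, so the p-values measure the spread between samples, which may be technical. The title of calcitriol replicate 6 names another vitamin D compound than its description, and it was kept in its group.

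The deposited values are linear intensity signals of 12488 probe sets per array. How the authors scaled or summarised them is not given in the sources used here. Between 1.27% and 3.53% of the deposited intensity values per array were below 0, and 765 were exactly 0, in numbers from 19 on placebo replicate 1 to 178 on naive replicate 2. Many of the exact zeros belong to probe sets that are bright on the other arrays and look like failed estimates. Of the exact zeros, 763 fall in 720 probe sets outside the controls, 688 of which were tested. Probe-level image files were not used here.

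Deposited signals were scaled to a common mean of 192.8 (leaving out the lowest and highest 2%), raised to a floor of 10% of it (19.3) and taken to log2. The 66 control probe sets were left out, and 12177 of the other 12422 probe sets were tested, those above the floor on at least 3 of 9 arrays. The remaining 245 were too dim. Linear models with empirical Bayes moderation and an intensity trend (limma 3.58.1 on R 4.3.3) gave the 3 comparisons from 1 fit over all 9 arrays, with 6 residual degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05 within each comparison, and errors of differences are standard errors (SE) of the fit. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the plots. The median SE of a log2 difference was 0.29, and its median 95% interval reached 0.64 to either side. These errors use 1 spread per probe set, pooled over the groups. Naive arrays varied more (median SD 0.36 log2) than placebo (0.23) and calcitriol arrays (0.25). The errors are therefore likely too wide for calcitriol against placebo and too narrow for the comparisons with naive. The fit was tested on log2 values simulated after scaling and filter, with 200 changed of 12177 probe sets in 20 simulations for each comparison. The changed probe sets were drawn from those with a mean above 2 times the floor in the reference group. Of 2-fold changes 39.8%, 36.0% and 42.4% were called in placebo against naive, calcitriol against placebo and calcitriol against naive, and of the calls 5.45%, 5.19% and 4.86% were false. A gene with all arrays of the reference group at the floor is given with a lower bound of its fold.

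Of all probe sets, 10855 had 1 gene symbol, 396 several and 1237 none, and no symbol was updated. Each of 8170 genes was represented by 1 probe set, a plain probe set where there was one and then the one with the highest mean, and 581 of these representatives were not plain. For 1997 genes with more than 1 tested probe set, named genes are given with the sign of the others where it was opposite. No genome positions were used.

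The comparisons, the gene lists and the rule for naming genes were set before the data were examined. Named genes were, for each comparison, the 10 largest rises and falls among probe sets past the threshold without overlap between groups. Where fewer than 10 passed, all were named, and 5 with the smallest unadjusted p filled a side and are given as not past the threshold. For each list, up to 4 members with the smallest unadjusted p were named. Vdr, Cyp24a1, Cyp27b1, Gapdh and Actb were always named, and Gapdh had only control probe sets. Other genes named as members past the threshold were chosen after their values were seen.

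The 31 lists held 912 genes, of which 719 were measured: MHC class II, MHC class I, interferon response, chemokines, cytokines, complement, T cell, B cell, monocyte, macrophage and microglia, neutrophil, mast cell, proliferation, astrocyte, oligodendrocyte and myelin, neuron, Schwann cell, endothelium, fibroblast and matrix, skeletal muscle, erythroid, cholesterol synthesis, cholesterol efflux, vitamin D, apoptosis and calpains, NF-kappa B, glucocorticoid-responsive, immediate early, heat shock, antioxidant, oxidative phosphorylation and ribosomal protein genes. They were written from general knowledge, share some genes (Mt2 is on 3 of them) and name functions, not sorted cells. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, with adjustment over the 31 lists. Two-sided exact permutation tests compared single values per array, and 1000 simulated series gave the share of probe sets expected to move back without any effect.

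Alternatives were values as deposited, quantile normalization, common median scaling, floors of 5% and 20%, log2 of the value plus a pseudocount, no filter, a filter on the mean, no trend, array weights, only the 2 groups compared, at least 1.5-fold, an estimated correlation between genes, fry, all probe sets of a gene averaged, and each array left out in turn. Exact zeros as missing was added after the data were seen.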

Results

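Gene expression was measured in spinal cord total RNA of B10.PL mice on 9 one-colour oligonucleotide arrays, 1 array per sample. The 9 samples formed 3 groups of 3: naive mice (replicates 2, 3 and 4), mice with experimental autoimmune encephalomyelitis (EAE, an autoimmune inflammation of the central nervous system used as a model of multiple sclerosis) given placebo (replicates 1, 5 and 10), and mice with EAE given 200 ng of calcitriol, the hormonal form of vitamin D (replicates 6, 7 and 8). Cords of the treated mice were taken 6 h after treatment. The title of calcitriol replicate 6 names the D2 form of the hormone, whereas the description of every sample names the D3 form. Median deposited signals were similar on all arrays, from 110.9 on naive replicate 4 to 135.8 on calcitriol replicate 7. After scaling, 6.12% to 11.3% of probe sets lay at the floor of 19.3 signal units. Log2 signals correlated across probe sets at 0.921 to 0.936 between placebo arrays and at 0.899 to 0.938 between calcitriol arrays, but at 0.765 to 0.878 between naive arrays, with naive replicate 2 in the lowest pair. The number of arrays, 3 per group, limits the precision of every value below.

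The control probe sets for beta-actin measured how far the labelled RNA reached from the 3′ end toward the 5′ end of the transcript. The 5′ minus 3′ log2 difference was -0.05 ± 0.19 (SD, n = 3) in naive cord, -0.80 ± 0.35 (SD, n = 3) in placebo-treated EAE and -0.67 ± 0.16 (SD, n = 3) in calcitriol-treated EAE. All EAE arrays lay below all naive arrays. The difference was -0.75 for placebo (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow, and 0.2 after Benjamini-Hochberg adjustment over 6 comparisons) and -0.62 for calcitriol (exact permutation p = 0.1, adjusted 0.2). Calcitriol and placebo arrays differed by 0.13 (exact permutation p = 0.6, adjusted 0.7), which turned to -0.23 under quantile normalization and -0.02 without placebo replicate 1. The Gapdh probe sets gave 0.59 ± 0.02 (SD, n = 2, since naive replicate 2 had an exact 0), 0.05 ± 0.40 (SD, n = 3) and 0.27 ± 0.13 (SD, n = 3) in naive, placebo and calcitriol arrays. Their exact permutation p was 0.2 and 0.1 against naive and 0.7 between the EAE groups (adjusted 0.3, 0.2 and 0.7). The beta-actin 5′ probe set itself ranged from 2940 to 6352 signal units on naive, 3047 to 6671 on placebo and 5433 to 8114 on calcitriol arrays. The 3′ probe set ranged from 2702 to 7557, 6567 to 8949 and 9690 to 12755, so for beta-actin the lower difference came with higher 3′ signal and not with lower 5′ signal. For Gapdh the 5′ signal was lower on the EAE arrays, at -0.28 log2 on average against naive. It overlapped, at 3584 to 6215 on naive, 2403 to 4709 on placebo and 3110 to 5400 on calcitriol arrays. The Gapdh 3′ signal was higher on all EAE arrays than on all naive arrays. The 18S ribosomal RNA control probe sets were also higher on the EAE arrays, by 2.14 (3′), 2.71 (5′) and 1.85 log2 (middle) on average. Naive and EAE arrays overlapped in each. Naive replicate 2 was the lowest array in all of them, at 83.4 (3′) and 106 signal units (5′) and below the floor in the middle. Naive replicates 3 and 4 had 1360 and 2173 (3′), 778 and 1492 (5′) and 128 and 170 (middle). The 18S averages therefore rest in large part on naive replicate 2. What caused these differences between naive and EAE arrays was not tested. The EAE arrays with the lower 5′ minus 3′ difference are those of the comparisons with naive cord described next.

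Placebo-treated EAE was compared with naive cord to find what EAE changed in the tissue. The labels name no placebo or treatment time for the naive mice, so the comparison cannot separate EAE from the placebo treatment. Genes called changed by EAE, here and below, are those that differed in this comparison. Among named genes past the threshold, Arg1, Serpina3n and B2m had the largest rises and Cplx1 the largest fall. Arg1, the arginase of alternatively activated macrophages, was at the floor on all 3 naive arrays and rose at least 59.5-fold (5.90 ± 0.21 log2, SE, n = 3 per group). Serpina3n, a protease inhibitor of reactive astrocytes, rose 39.3-fold (5.30 ± 0.22 log2, SE). B2m, the light chain of MHC class I, rose by 4.32 ± 0.76 log2 (SE). Cplx1, which encodes the presynaptic protein complexin 1, was 2.71-fold lower (-1.44 ± 0.25 log2, SE). Bcan, the matrix proteoglycan brevican, was 1.90-fold lower (-0.92 ± 0.17 log2, SE). The limma adjusted p-values (Benjamini-Hochberg) of these 5 genes were 1.68e-06, 4.91e-06, 0.0356, 0.0333 and 0.0386.

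In all, 114 of 12177 probe sets changed in limma at a Benjamini-Hochberg adjusted p under 0.05, 108 higher and 6 lower in EAE. They stood for 80 genes, 76 higher and 4 lower, and 17 of the probe sets had no single gene symbol. Of the 114 differences, 107 were at least 2-fold and 57 at least 4-fold. Over all tested probe sets, 14.5% had groups without overlap, where chance gives 10%. Ctsc, the lysosomal protease cathepsin C, rose at least 18.0-fold (4.17 ± 0.34 log2, SE, limma adjusted p = 0.000783). Other large rises were of Gbp2, an interferon-induced GTPase (13.9-fold, limma adjusted p = 0.0386), and Ifitm3, an interferon-induced membrane protein (3.59 log2, limma adjusted p = 0.00886). Chil3, a chitinase-like protein of macrophages and neutrophils, rose 10.1-fold, the matrix protein fibronectin (Fn1) 9.93-fold, and Lyz2, the lysozyme of myeloid cells, and Chil1, another chitinase-like protein, at least 9.69-fold each. Septin4, a cytoskeletal septin, fell by 1.30 log2 (limma adjusted p = 0.0307) and Timm9, a mitochondrial import protein, fell by 1.42 log2 (limma adjusted p = 0.049), the latter with 2 of 3 placebo arrays at the floor. Pdyn, the precursor of dynorphin, stood at -0.60 ± 0.12 log2 (SE) and just missed the threshold (limma adjusted p = 0.054). The count depended on single arrays: it was 176 without naive replicate 2, 46 without naive replicate 3, 49 without naive replicate 4, 34 without placebo replicate 1, 20 without placebo replicate 5 and 75 without calcitriol replicate 6, which enters through the shared estimate of the spread. It was 639 with array weights, where 462 were higher and 177 lower, and 61 when only the naive and placebo arrays were fitted. The weights were 4.38 on naive replicate 3 and 0.26 and 0.41 on naive replicates 2 and 4. With weights the naive group therefore rested mostly on replicate 3.

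The monocyte, neutrophil and interferon response lists shifted up by camera at the preset correlation. Of 38 measured monocyte, macrophage and microglia markers, 8 rose, 0 fell and 30 did not pass the test (20 rose and 1 fell when adjusted over the list alone). Their median difference was 0.74 log2 (camera, Benjamini-Hochberg adjusted p = 1.78e-18, and adjusted p = 0.0783 with an estimated correlation). Beside Ctsc and Lyz2, Lcp1, an actin-bundling protein of leukocytes, rose by 1.40 log2 (its other probe set went the opposite way) and Cd53, a leukocyte tetraspanin at the floor in naive cord, by at least 2.94 log2. Of 16 neutrophil markers, 4 rose and 12 did not pass (5 rose when adjusted over the list alone): Chil3, the calprotectin subunits S100a8 (3.16 ± 0.28 log2, SE) and S100a9 (at least 2.22 log2, with all naive arrays at the floor), and the siderophore-binding protein Lcn2 (2.01 log2). The list shifted up by camera (adjusted p = 1.35e-06, Benjamini-Hochberg, and adjusted p = 0.0783 with an estimated correlation). Of 27 interferon response genes, 5 rose and 22 did not pass (13 rose when adjusted over the list alone). Their median was 0.77 log2 (camera adjusted p = 8.21e-11, Benjamini-Hochberg, and adjusted p = 0.0969 with an estimated correlation). The GTPases Iigp1 (2.63 log2) and Gbp3 (1.98 log2) were among them. All of these lists were higher in the same arrays that had the lower beta-actin 5′ minus 3′ difference.

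The MHC, complement and chemokine lists shifted up at the preset correlation in the same arrays. Of 11 MHC class I and peptide loading genes, 1 rose, B2m, and 10 did not pass (4 rose when adjusted over the list alone). H2-D1, a class I heavy chain, stood at 2.38 ± 0.47 log2 (SE, limma adjusted p = 0.0565). Of 12 MHC class II and antigen processing genes, 1 rose and 11 did not pass (4 rose when adjusted over the list alone). The member that rose was Ctss, the protease that trims the class II invariant chain (2.35 log2), while the invariant chain itself, Cd74, stood at 1.86 ± 0.47 log2 (SE, limma adjusted p = 0.152). Both lists shifted up by camera (Benjamini-Hochberg adjusted p = 1.43e-07 and 2.87e-05, and adjusted p = 0.0783 with an estimated correlation for each). Of 13 complement genes, 3 rose, the C1q chains C1qa (1.75 log2), C1qb (2.72 log2, with its other probe set opposite in sign) and C1qc (2.17 log2), and 10 did not pass (3 rose when adjusted over the list alone). The complement list shifted up (camera, Benjamini-Hochberg adjusted p = 0.00294, and adjusted p = 0.0959 with an estimated correlation), although its median, 0.22 log2, turned negative in 2 of the alternative settings. Of 34 chemokines and receptors, 3 rose, Ccl9 (2.06 log2), Cxcl10 (2.08 log2) and Ccl7 (at least 1.95 log2, with all naive arrays at the floor), all attractants of leukocytes, and 31 did not pass (6 rose when adjusted over the list alone). This list shifted up as well (camera, Benjamini-Hochberg adjusted p = 0.000616, and adjusted p = 0.128 with an estimated correlation), but not with the filter on the mean (camera adjusted p = 0.392).

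Lymphocyte markers were not shifted. Of 26 T cell markers none passed the limma test at a Benjamini-Hochberg adjusted p under 0.05 (0 also when adjusted over the list alone), with a median of -0.09 log2 (camera adjusted p = 0.374). Of 16 B cell and plasma cell markers none passed either (0 also when adjusted over the list alone), with a median of -0.17 log2 (camera adjusted p = 0.374). Among T cell genes, Ccl5, a chemokine of activated T cells, stood at 1.07 ± 0.46 log2 (SE, limma adjusted p = 0.494) and Zap70, the T cell receptor kinase, at -0.43 ± 0.16 log2 (SE, limma adjusted p = 0.387). Of 45 cytokines and receptors none passed (0 also when adjusted over the list alone), with a median of 0.07 log2 (camera adjusted p = 0.0542), and Il1rn, the interleukin-1 receptor antagonist, stood at 2.51 ± 0.59 log2 (SE, limma adjusted p = 0.12). Mast cell (9 genes, median 0.17 log2, camera adjusted p = 0.631), proliferation (34 genes, 0.04 log2, 0.714), erythroid (8 genes, 0.08 log2, 0.631) and skeletal muscle (17 genes, -0.10 log2, 0.702) lists were not shifted, with 0 members past the test.

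Of the lists of resident neural cells, neuron and oligodendrocyte genes shifted down and astrocyte genes up at the preset correlation. Of 43 neuron markers, 1 fell, Cplx1, and 42 did not pass (1 fell when adjusted over the list alone). Their median was -0.33 log2, with 34 of 43 lower (camera, Benjamini-Hochberg adjusted p = 3.58e-05, and adjusted p = 0.0969 with an estimated correlation). The array medians of this list overlapped between the groups: relative to the naive mean they were 0.28, -0.16 and -0.09 log2 on naive replicates 2, 3 and 4, and -0.11, -0.47 and -0.38 log2 on placebo replicates 1, 5 and 10. Nefm, a neurofilament subunit, stood at -1.20 ± 0.34 log2 (SE, limma adjusted p = 0.22). Of 17 oligodendrocyte and myelin genes none passed over all probe sets and 7 fell when adjusted over the list alone. Their median was -0.20 log2 (camera, Benjamini-Hochberg adjusted p = 0.00159, and adjusted p = 0.0783 with an estimated correlation). Here too the array medians overlapped, at 0.33, -0.11 and -0.21 log2 on the naive and -0.19, -0.43 and -0.43 log2 on the placebo arrays, and the median difference ran from -0.36 to -0.06 log2 over the settings tried. Ugt8a, which makes the myelin lipid galactosylceramide, stood at -1.64 ± 0.36 log2 (SE, limma adjusted p = 0.0911) and Mog, a myelin surface protein, at -1.33 ± 0.30 log2 (SE, limma adjusted p = 0.106). Of 23 astrocyte genes, 3 rose, Serpina3n and the metallothioneins Mt1 (1.90 log2) and Mt2 (2.04 log2), and 20 did not pass (5 rose and 1 fell when adjusted over the list alone). The list shifted up (camera, Benjamini-Hochberg adjusted p = 0.000439, and adjusted p = 0.0783 with an estimated correlation). The metallothioneins bind zinc in many cell types. Of 6 Schwann cell and nerve root markers, 1 rose, S100a4 (0.86 log2), a calcium-binding protein also made by leukocytes and fibroblasts, and 5 did not pass (1 rose when adjusted over the list alone). That list was not shifted, and its median, -0.24 log2, was opposite in sign to its mean and its test, 0.02 log2 and higher (camera adjusted p = 0.952).

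Among vessel, matrix and lipid genes, 1 of 23 endothelium and leukocyte adhesion genes rose (1 also when adjusted over the list alone), Ly6e, which is also induced by interferon, by 2.12 log2. The list shifted up (camera, Benjamini-Hochberg adjusted p = 0.0243, and adjusted p = 0.093 with an estimated correlation). This call was lost with array weights (camera adjusted p = 0.0853, Benjamini-Hochberg) and without naive replicate 2 (0.163). Of 33 fibroblast, meninges and matrix genes, 2 rose, Fn1 and the basement membrane collagen Col4a1 (1.42 log2), and 31 did not pass (3 rose when adjusted over the list alone). They shifted up as a list (camera, Benjamini-Hochberg adjusted p = 0.00447, and adjusted p = 0.0783 with an estimated correlation). Of 16 cholesterol efflux and lipid transport genes, 2 rose, the lipid carrier Apod (2.07 log2) and the lipid droplet protein Plin2 (1.42 log2), and 14 did not pass (4 rose and 1 fell when adjusted over the list alone). This list too shifted up (camera, Benjamini-Hochberg adjusted p = 0.0243, and adjusted p = 0.0955 with an estimated correlation). Its median was 0.04 log2, with 9 of 16 members higher. The call was also lost with both other floors, no filter, the filter on the mean and array weights, and without naive replicate 4 (camera adjusted p = 0.107, Benjamini-Hochberg) and placebo replicate 10 (0.142). The 20 cholesterol synthesis genes were not shifted (median -0.02 log2, camera adjusted p = 0.644).

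Lists of stress and housekeeping genes shifted as well. Of 23 glucocorticoid-responsive genes, 5 rose, among them the transcription factors Cebpd (3.26 ± 0.27 log2, SE) and Cebpb (2.86 log2), which are also induced in inflammation, and 18 did not pass (7 rose and 1 fell when adjusted over the list alone). The list shifted up (camera, Benjamini-Hochberg adjusted p = 6.35e-07, and adjusted p = 0.0783 with an estimated correlation). Of 26 immediate early genes, Fos, a transcription factor gene switched on within minutes of stimulation, rose (1.60 log2, and 6 rose when adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.000622, and adjusted p = 0.0783 with an estimated correlation). Of 24 ribosomal protein genes, 2 rose, Rplp0 (1.14 log2) and Rpl10a (1.11 log2), and 22 did not pass (5 rose when adjusted over the list alone). Their median of 0.38 log2 was positive in all settings tried (camera, Benjamini-Hochberg adjusted p = 7.05e-07, and adjusted p = 0.0783 with an estimated correlation). Of 35 oxidative phosphorylation genes none passed (0 also when adjusted over the list alone), with a median of -0.25 log2 (camera, Benjamini-Hochberg adjusted p = 0.00478, and adjusted p = 0.227 with an estimated correlation). The apoptosis and calpain (49 genes, 0 past the test, 1 rose when adjusted over the list alone), NF-kappa B (17 genes, 0 past the test, 2 rose when adjusted over the list alone) and antioxidant (31 genes, Mt1 and Mt2 past the test, 3 rose when adjusted over the list alone) lists shifted up. Their camera adjusted p-values were 0.0113, 0.013 and 0.0428 (Benjamini-Hochberg), and adjusted p = 0.0783, 0.209 and 0.128 with an estimated correlation. The apoptosis call was lost without naive replicate 3 (camera adjusted p = 0.0633, Benjamini-Hochberg), and the NF-kappa B call without naive replicate 2 (0.119) and placebo replicate 5 (0.156). The antioxidant call was lost without naive replicates 3 (0.182) and 4 (0.118) and placebo replicate 5 (0.201), as deposited, with the filter on the mean and with probe sets averaged. The oxidative phosphorylation call was lost without naive replicate 2 (0.122) and with the filter on the mean. The 29 heat shock and folding genes (median 0.14 log2, camera adjusted p = 0.234) and the 26 vitamin D target and metabolism genes (median -0.05 log2, camera adjusted p = 0.538, 1 rose and 1 fell when adjusted over the list alone) were not shifted. Actb, often used as a reference gene, rose by 2.08 ± 0.33 log2 (SE, limma adjusted p = 0.024) in its representative probe set. The sense-strand control probe sets for beta-actin rose less, by 0.51 (5′), 0.88 (middle) and 1.19 log2 (3′) on average over both EAE groups. In each of them the placebo and naive arrays overlapped. In all, 20 of 31 lists shifted by camera, 17 up and 3 down, 18 lists moved by fry, which lost the NF-kappa B (adjusted p = 0.0849) and oxidative phosphorylation (0.0881) lists. With an estimated correlation 0 passed in camera, where 15 had an unadjusted p under 0.05.

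**Figure D1:**
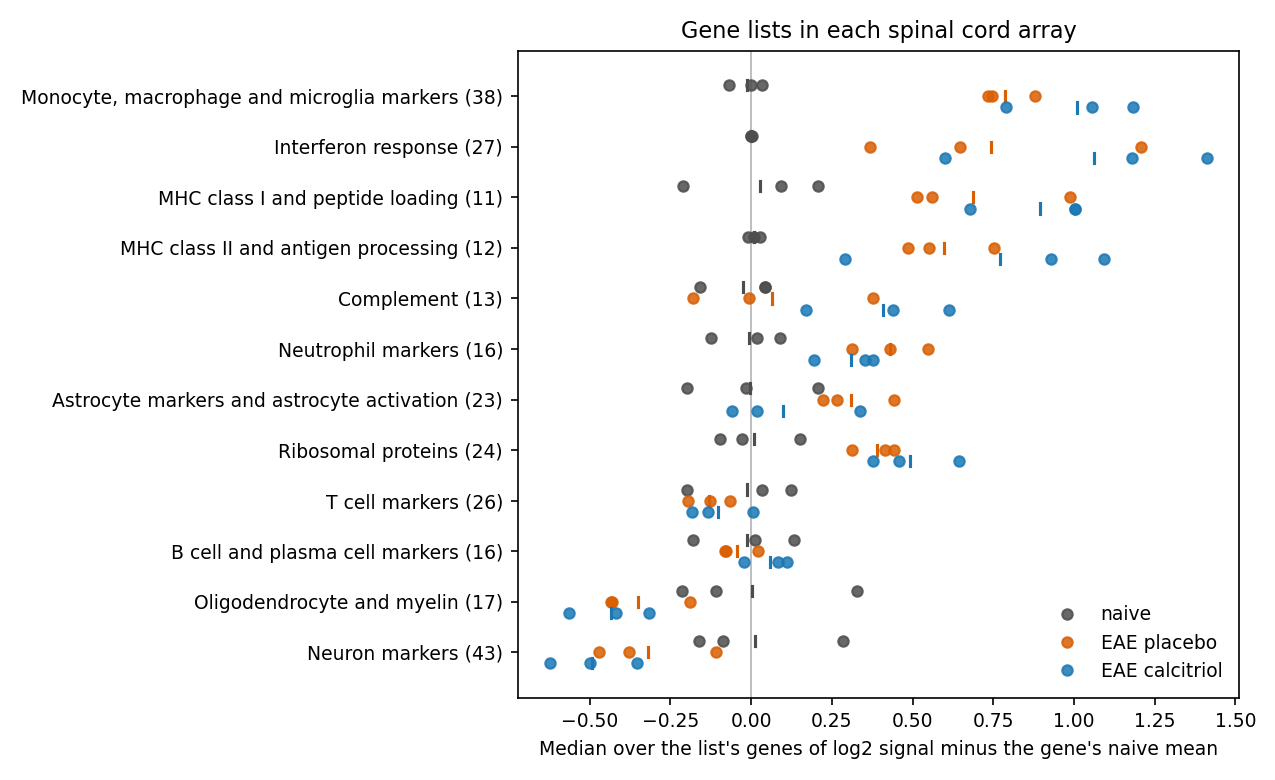
Median over the genes of 12 fixed lists of the log2 signal minus each gene's naive mean, for each of the 9 arrays, with the number of measured genes in parentheses and a vertical tick at each group mean. The monocyte, macrophage and microglia medians of the 6 EAE arrays lie between 0.74 and 1.18, whereas the T cell medians of all 9 arrays lie between -0.20 and 0.12.

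Calcitriol-treated EAE was compared with placebo-treated EAE to find what the hormone changed within 6 h. No probe set passed the threshold. Arg1 had the smallest unadjusted p among named genes that were higher after calcitriol, at 2.12-fold (1.08 ± 0.21 log2, SE, n = 3 per group, limma adjusted p = 1), with all 3 calcitriol arrays above all 3 placebo arrays. Ifit1, an interferon-induced gene at the floor on 2 placebo arrays, stood 4.82-fold higher (2.27 ± 0.50 log2, SE), Fmr1, an RNA-binding protein, 2.94-fold higher (1.56 ± 0.32 log2, SE, with its other probe set opposite in sign), and Iqgap2, a scaffold protein, 2.49-fold higher (1.32 ± 0.30 log2, SE). On the lower side stood Nnat, the neural membrane protein neuronatin (-0.69 ± 0.13 log2, SE), Ckb, the brain form of creatine kinase (-1.06 ± 0.22 log2, SE), Rarg, a retinoic acid receptor (-1.62 ± 0.33 log2, SE, at the floor on 2 calcitriol arrays) and Tle5, a transcriptional corepressor (-0.61 ± 0.13 log2, SE). None of these 8 genes passed the test. Groups did not overlap for 9.99% of all tested probe sets in this comparison, where chance gives 10%.

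The limma count was 0 of 12177 at a Benjamini-Hochberg adjusted p under 0.05, with 314 probe sets at an unadjusted p under 0.05 where 608.85 would arise by chance. It was also 0 with array weights (627 unadjusted) and when only the 2 EAE groups were fitted (541 unadjusted). It was 1 without calcitriol replicate 6, Myl6, a myosin light chain listed at exactly 0 on 2 calcitriol arrays, and 1 without calcitriol replicate 7, a probe set without a gene symbol, also at exactly 0 on both calcitriol arrays left. In simulated data of this comparison with 200 changed of 12177 probe sets, 36.0% of 2-fold, 77.7% of 4-fold and 92.2% of 8-fold changes were called. The changed probe sets were drawn from those with a placebo mean above 2 times the floor, so these shares do not cover dimmer ones. In the real data, the median 95% interval of a difference reached 0.64 log2 to either side. The simulated shares and the interval use the spread pooled with the more variable naive arrays, so they may understate the precision of this comparison. With only the EAE groups fitted, the unadjusted count was 541 in place of 314, so the pooled test was the more conservative. No call was made for genes that respond directly to vitamin D. Cyp24a1, the enzyme that degrades calcitriol and a standard target of its receptor, stood at 0.33 ± 0.48 log2 (SE) and the receptor gene Vdr at -0.03 ± 0.59 log2 (SE), both dim. Scaled Cyp24a1 signals were 47.6 to 106 on the calcitriol arrays and 48.9 to 74.3 on the placebo arrays. Cyp27b1, which makes calcitriol, was listed at exactly 0 on placebo replicate 10, at 449 and 417 on the other placebo arrays, and at 583, 513 and 416 on the calcitriol arrays. Of the 26 vitamin D targets and metabolism genes none passed (0 also when adjusted over the list alone), with a median of 0.07 log2 and 16 of 26 higher (camera adjusted p = 0.142), and Ccnc, a cyclin, had the smallest p (0.79 ± 0.31 log2, SE).

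At the preset correlation, 5 of 31 lists shifted between the EAE groups, 3 up and 2 down, and no member passed the limma test over all probe sets at a Benjamini-Hochberg adjusted p under 0.05. The monocyte, macrophage and microglia list shifted up, with 32 of 38 members higher and a median of 0.26 log2 (camera, Benjamini-Hochberg adjusted p = 1.08e-05, and adjusted p = 0.614 with an estimated correlation). Its members with the smallest p were Fcgr3, an Fc receptor (1.05 ± 0.36 log2, SE), Lyz2 (1.22 ± 0.46 log2, SE, with its other probe set opposite in sign) and Lgals3, a lectin of macrophages (1.49 ± 0.60 log2, SE). The interferon response list shifted up, with 22 of 27 members higher and a median of 0.39 log2 (camera, Benjamini-Hochberg adjusted p = 2.62e-05, and adjusted p = 0.614 with an estimated correlation). Ifit1 was the single member of the 5 shifted lists past the test when adjusted over the list alone, and Irgm1, an interferon-induced GTPase, stood at 1.58 ± 0.47 log2 (SE). The MHC class II and antigen processing list shifted up, with 10 of 12 members higher and a median of 0.29 log2 (camera, Benjamini-Hochberg adjusted p = 0.0127, and adjusted p = 0.614 with an estimated correlation). Its array medians were 0.93, 0.29 and 1.09 log2 above naive on calcitriol replicates 6, 7 and 8 and 0.49, 0.75 and 0.55 log2 on the placebo arrays, so replicate 7 lay below all placebo arrays. Calcitriol and placebo arrays also overlapped in the other 4 shifted lists: the array median of calcitriol replicate 7 was 0.79 log2 for the monocyte, 0.60 for the interferon, 0.34 for the astrocyte and -0.35 for the neuron list, against placebo ranges of 0.74 to 0.88, 0.37 to 1.21, 0.22 to 0.44 and -0.47 to -0.11. The neuron list shifted down, with 32 of 43 members lower and a median of -0.15 log2 (camera, Benjamini-Hochberg adjusted p = 0.011, and adjusted p = 0.614 with an estimated correlation). The astrocyte list shifted down, with 17 of 23 members lower and a median of -0.25 log2 (camera, Benjamini-Hochberg adjusted p = 0.0322, and adjusted p = 0.614 with an estimated correlation). Thy1, a neuronal surface protein, stood at -0.63 ± 0.17 log2 (SE), Ache, acetylcholinesterase, at -0.54 ± 0.17 log2 (SE), and Mt3, the metallothionein of the nervous system, at -0.70 ± 0.27 log2 (SE). No list passed without the preset correlation: fry moved 0 lists (smallest adjusted p = 0.786, with 1 list at an unadjusted p under 0.05), and camera with an estimated correlation shifted 0 (0 unadjusted). Camera at the preset correlation shifted 3 lists with array weights, 1 without calcitriol replicate 6, 2 without placebo replicate 1, 3 without placebo replicate 10 and 3 without calcitriol replicate 8. The monocyte, macrophage and microglia list kept its call with each array left out, with a median from 0.13 log2 without calcitriol replicate 8 to 0.39 log2 without placebo replicate 5. MHC class II lost it without placebo replicates 1 and 10 and calcitriol replicates 6 and 8 (camera adjusted p = 0.114, 0.0637, 0.224 and 0.226, Benjamini-Hochberg). The interferon list lost it without placebo replicate 10 (0.103, median 0.20 log2) and calcitriol replicate 6 (0.050001, 0.33 log2). The neuron list lost it without placebo replicate 1 (0.251, median -0.08 log2) and calcitriol replicate 6 (0.050001, -0.12 log2). The astrocyte list lost it without placebo replicate 1 (0.114, median -0.19 log2) and calcitriol replicates 6 (0.224, -0.15 log2) and 8 (0.269, -0.15 log2).

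The other 26 lists were not shifted between the EAE groups. The camera adjusted p-values (Benjamini-Hochberg) nearest the threshold were 0.068 for MHC class I (median 0.30 log2), 0.0707 for chemokines (median 0.08 log2, with Ccl2, which attracts monocytes, at 2.38 ± 1.02 log2, SE) and 0.114 for oligodendrocyte and myelin genes (median -0.24 log2). T cell (median 0.11 log2) and B cell markers (median 0.10 log2) had adjusted p-values of 0.445 and 0.349, and apoptosis and calpain genes (median 0.05 log2) one of 0.686. Adjusted over the list alone, Prph, the neurofilament protein peripherin in the Schwann cell and nerve root list, fell by at least 1.03 log2, with all 3 calcitriol arrays at the floor, and no other member of these lists passed. For proliferation the median and mean were opposite in sign to the test (-0.02 and -0.02 log2 against higher), for cholesterol efflux the mean was opposite to the median and test (-0.01 against 0.06 log2), and for oxidative phosphorylation the mean was opposite to the median and test (0.01 against -0.03 log2).

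**Figure D2:**
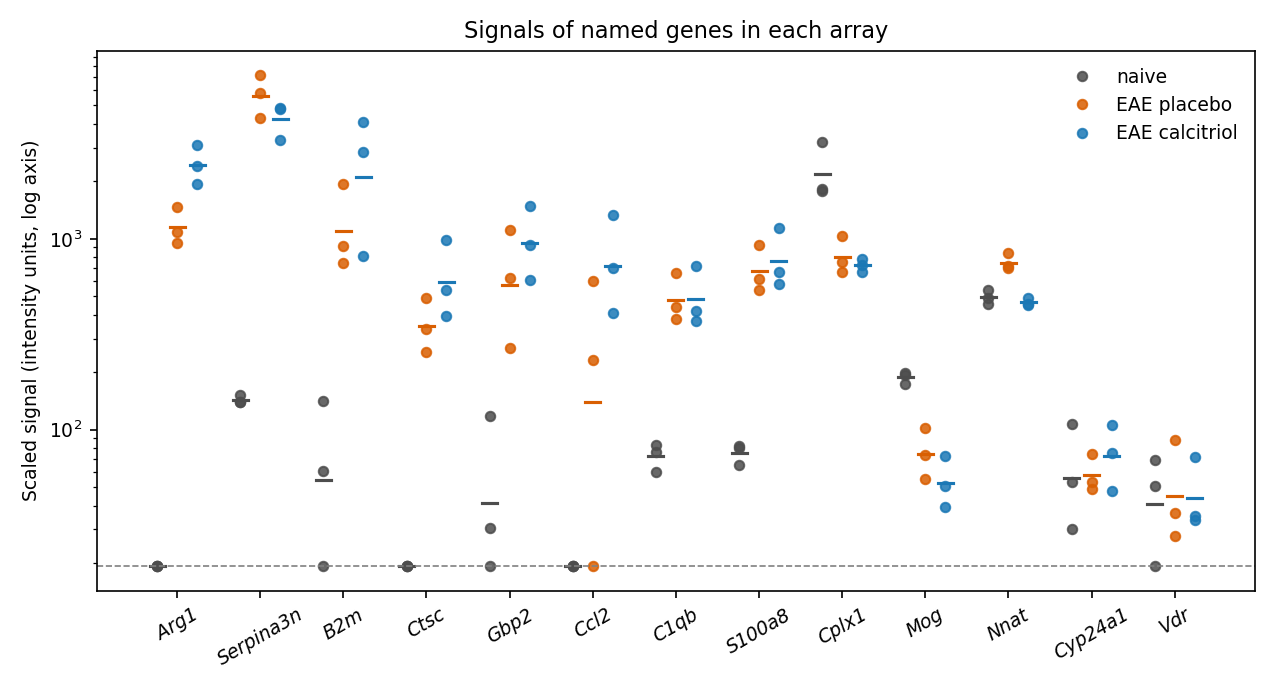
Scaled signal (log axis, intensity units) of 13 named genes on each of the 9 arrays, with a bar at each group's geometric mean and a dashed line at the floor of 19.3. Arg1 is at the floor on the 3 naive arrays, between 953 and 1465 on the placebo arrays and between 1941 and 3108 on the calcitriol arrays, whereas Cyp24a1 overlaps between the groups.

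Whether calcitriol moved the EAE-changed genes back toward the naive level was read from the 114 probe sets changed by EAE. Of these, 31 (27.2%) lay nearer to naive after calcitriol than after placebo and 83 lay further away. In each other setting the share was taken over the probe sets which that setting called, not over these 114. It was 44.3% with array weights and, with 1 array left out, ran from 20% without calcitriol replicate 6 to 40.0% without placebo replicate 5. Of the 114, 30 of the 108 that EAE raised and 1 of the 6 that it lowered moved back. Because the probe sets were chosen on the placebo arrays, a calcitriol group that did not differ from placebo would appear to move back for many of them. In 1000 simulated series without such a difference, 67.9% moved back (SD 1.97), over an average of 483 changed probe sets per simulation. Over the 114 with the smallest p in each, the share was 64.5% (SD 4.44). In 0 of 1000 simulations was either share as low as 27.2%. The simulations treated probe sets as independent, so their spread is too narrow. They also took the observed means as true and used 1 spread per probe set, pooled over the groups. Naive arrays varied more (median SD 0.36 log2) than placebo (0.23) and calcitriol arrays (0.25), so placebo noise was likely simulated too large. The simulated shares are therefore likely too high, and 0 of 1000 overstates the contrast with 27.2%. Averaged per array, the shift along the EAE change was 2.04, 2.29 and 1.95 log2 on placebo replicates 1, 5 and 10 and 2.24, 2.11 and 2.64 log2 on calcitriol replicates 6, 7 and 8. The group means differed by 0.23 log2, and the arrays of both groups overlapped (two-sided exact permutation p = 0.3 against a difference of 0, where 0.1 is the smallest possible). Because of the same choice of probe sets, simulated series without a difference gave -0.15 log2 (SD 0.04) over 114 probe sets, and 0 of 1000 a value as high as 0.23. With the pooled spread, -0.15 log2 likely lies too far toward naive as well.

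**Figure D3:**
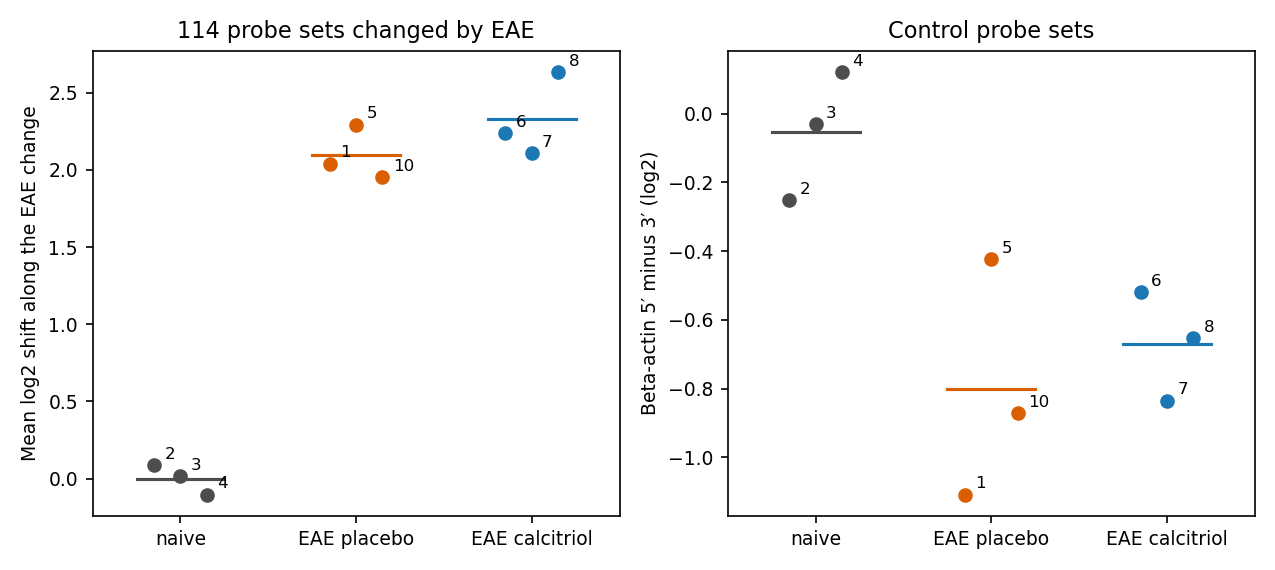
Left, mean log2 shift along the EAE change over the 114 probe sets changed by EAE, and right, beta-actin 5′ minus 3′ log2 difference of the control probe sets, for each array (points labelled by replicate) with a bar at each group mean. Placebo (1.95 to 2.29) and calcitriol arrays (2.11 to 2.64) overlap on the left, and all EAE arrays lie below all naive arrays on the right.

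Calcitriol-treated EAE was compared with naive cord to describe the treated tissue as a whole. Among named genes past the threshold, Arg1, B2m and Ccl2 had the largest rises and Ttc3 and Mog the largest falls. Arg1 rose at least 126-fold (6.98 ± 0.21 log2, SE, n = 3 per group, limma adjusted p = 3.4e-07) and B2m 38.6-fold (5.27 ± 0.76 log2, SE, limma adjusted p = 0.00867). Ccl2, at the floor on all naive arrays, rose at least 37.6-fold (5.23 ± 1.02 log2, SE, limma adjusted p = 0.0327), and Serpina3n rose 29.7-fold (4.89 ± 0.22 log2, SE, limma adjusted p = 1.04e-05). Among genes that fell, Ttc3, a ubiquitin ligase, was 5.69-fold lower (-2.51 ± 0.49 log2, SE, limma adjusted p = 0.0322) and Mog 3.56-fold lower (-1.83 ± 0.30 log2, SE, limma adjusted p = 0.0158).

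In limma, 244 of 12177 probe sets changed at a Benjamini-Hochberg adjusted p under 0.05, 205 higher and 39 lower than naive, for 170 genes (137 higher, 33 lower). Of the 244, 207 differed at least 2-fold and 101 at least 4-fold, and 36 had no single gene symbol. Over all tested probe sets, 16.1% had groups without overlap, where chance gives 10%. Without scaling, 229 were higher and 13 lower, a share of 94.6% higher in place of 84.0%. The further large rises were of Ctsc (at least 30.8-fold), Ifitm3 (23.6-fold), Gbp2 (4.52 log2), Lyz2 (at least 22.5-fold), Lgals3 (at least 22.3-fold) and Chil3 (17.6-fold). The further falls included Septin4 (-1.61 log2), Cplx1 (-1.59 log2), Fxyd7, a regulator of the sodium pump in brain (-1.59 log2), Itgb4, a laminin receptor subunit (-1.57 log2), Fez1, an axonal transport adaptor (-1.47 log2), Tubb4a, a tubulin of neurons and oligodendrocytes (-1.44 log2), Timm9 (-1.43 log2) and Car2, a carbonic anhydrase of oligodendrocytes (-1.41 log2). The count was 392 without naive replicate 2, 115 without naive replicate 3, 130 without calcitriol replicate 6, 75 without calcitriol replicate 8, 1014 with array weights (653 higher and 361 lower) and 118 when only the naive and calcitriol arrays were fitted. With weights the naive group again rested mostly on replicate 3. As in placebo-treated EAE, these arrays differed from naive in the beta-actin 5′ minus 3′ difference, by -0.62 log2.

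By list, 16 of 38 monocyte, macrophage and microglia markers rose and 22 did not pass (24 rose and 1 fell when adjusted over the list alone). Their median was 0.99 log2 (camera, Benjamini-Hochberg adjusted p = 1.9e-22, and adjusted p = 0.0612 with an estimated correlation). Of 27 interferon response genes 8 rose (18 when adjusted over the list alone; median 1.19 log2, camera adjusted p = 1.25e-14, Benjamini-Hochberg, and adjusted p = 0.0674 with an estimated correlation). Iigp1 (3.53 log2) and Ifit3 (2.71 log2) were among them. MHC class I (4 of 11 rose, 8 when adjusted over the list alone) and MHC class II genes (4 of 12 rose, 7 when adjusted over the list alone) shifted up (camera, Benjamini-Hochberg adjusted p = 2.27e-08 and 1.68e-07, and adjusted p = 0.0612 with an estimated correlation). H2-D1 rose by 3.05 log2 and Cd74 by 2.57 log2. Chemokines (7 of 34 rose, 9 rose and 1 fell when adjusted over the list alone), complement (3 of 13 rose, 4 when adjusted over the list alone) and neutrophil markers (4 of 16 rose, 5 when adjusted over the list alone) shifted up. Their camera adjusted p-values were 6.1e-05, 0.000318 and 6.1e-05 (Benjamini-Hochberg), and adjusted p = 0.0978, 0.0612 and 0.0612 with an estimated correlation. The chemokine call was lost with the filter on the mean (median 0.11 log2, camera adjusted p = 0.302, Benjamini-Hochberg). Of 45 cytokines and receptors Il1rn rose (3.10 log2, and 3 rose when adjusted over the list alone; camera adjusted p = 0.0132, Benjamini-Hochberg, and adjusted p = 0.202 with an estimated correlation), a call lost with array weights, with fry (adjusted p = 0.122) and without naive replicate 2 (camera adjusted p = 0.18). Of 26 T cell markers none passed (1 rose when adjusted over the list alone; median -0.09 log2 and mean 0.01 log2, opposite in sign, camera adjusted p = 0.782). All of these values come from the arrays with the lower beta-actin 5′ minus 3′ difference.

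Of 43 neuron markers 2 fell and 41 did not pass (14 fell when adjusted over the list alone). Their median was -0.53 log2, with 36 of 43 lower (camera, Benjamini-Hochberg adjusted p = 1.01e-07, and adjusted p = 0.0612 with an estimated correlation). Cplx1 and Ache fell, the latter by 0.78 log2. Of 17 oligodendrocyte and myelin genes 3 fell, Mog, Car2 and Gsn, an actin-severing protein (-0.92 log2), and 14 did not pass (8 fell when adjusted over the list alone). The list shifted down (camera, Benjamini-Hochberg adjusted p = 0.000246, and adjusted p = 0.0612 with an estimated correlation). Ribosomal protein genes (2 of 24 rose, 11 rose and 1 fell when adjusted over the list alone; camera adjusted p = 3.45e-06, Benjamini-Hochberg, and adjusted p = 0.0612 with an estimated correlation) shifted up. Glucocorticoid-responsive (6 of 23 rose), immediate early (3 of 26 rose), matrix (3 of 33 rose), lipid transport (2 of 16 rose and 1 fell), apoptosis and calpain (1 of 49 rose) and NF-kappa B lists (2 of 17 rose) shifted up too. Their camera adjusted p-values (Benjamini-Hochberg) were 1.24e-07, 0.000246, 0.00269, 0.0208, 0.0092 and 0.0177, and adjusted p = 0.0612, 0.0612, 0.0612, 0.0796, 0.0612 and 0.229 with an estimated correlation. The lipid transport call was lost with array weights and without naive replicates 2 (camera adjusted p = 0.0522, Benjamini-Hochberg) and 4 (0.0715) and calcitriol replicate 6 (0.0516), and the NF-kappa B call without naive replicate 2 (0.101). Adjusted over the list alone, 10, 3, 6, 4, 1 and 2 of their members rose, and 3 matrix members and 1 lipid transport member fell. The lipid transport member that fell, Pltp, transfers phospholipids between lipoproteins (-1.27 log2), and the apoptosis member that rose was Gadd45g, a stress-induced gene (0.96 log2). Oxidative phosphorylation genes shifted down with 0 members past the test (median -0.19 log2, camera adjusted p = 0.0078, Benjamini-Hochberg, and adjusted p = 0.25 with an estimated correlation), a call lost without naive replicate 2 (camera adjusted p = 0.112). Of 26 vitamin D genes 1 rose, Cd14, a lipopolysaccharide receptor of monocytes (1.04 log2), and 1 fell, Car2, and the list was not shifted (camera adjusted p = 0.572). Neither were the astrocyte list, although Serpina3n, Mt2 and the protease inhibitor Timp1, the last with its other probe set opposite in sign, rose (3 of 23, camera adjusted p = 0.0787, 5 rose and 2 fell when adjusted over the list alone), nor the endothelium list, where Ly6e, its other probe set opposite in sign, rose (1 of 23, camera adjusted p = 0.102). The median of the 29 heat shock genes, -0.01 log2, was opposite in sign to their mean and test, 0.05 log2 and higher (camera adjusted p = 0.572). In all, 18 lists shifted by camera, 15 up and 3 down, and 18 moved by fry. Fry lost the cytokine, NF-kappa B (0.0521) and oxidative phosphorylation (0.0901) lists and gained the astrocyte (0.016), endothelium (0.0409) and antioxidant (0.0353) lists. With an estimated correlation 0 passed in camera, where 15 had an unadjusted p under 0.05.

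Both EAE groups were set against the same naive arrays, so part of what they share comes from those arrays. Across probe sets, which are not independent replicates, the differences from naive correlated at 0.801, where simulated unchanged groups against the same controls gave 0.501. Their covariance was 0.247, against 0.0840 in the simulation, a difference of 0.163. The simulation used 1 spread per probe set, but naive arrays varied more (median SD 0.36 log2) than placebo (0.23) and calcitriol arrays (0.25). The simulated correlation and covariance are therefore likely too low, and the difference of 0.163 likely too large. Of the changed probe sets, 102 were higher and 6 lower in both comparisons, where independent lists would share 1.82 and 0.0192. Simulated unchanged groups shared 0, but groups without any difference give hardly any calls that could be shared. Neither figure measures how much of the overlap comes from the shared naive arrays. A further 6 passed in placebo alone and 136 in calcitriol alone, but as no probe set differed between the EAE groups in limma, these are not shown to differ. With 3 naive arrays the controls could not be split into parts of at least 2 arrays, and part of the excess may come from them.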

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

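The tests of a lower neural share, of naive replicate 2 and of dim T cell genes were chosen after the result was seen. A signal outside the probe sets compared was flagged in the controls. A pair of antisense-strand control probe sets for beta-actin, at the 3′ end and the middle, were higher on all 6 EAE arrays than on the 3 naive arrays, by 1.264 and 1.824 log2. Their scaled signals ran from 154 to 347 in naive, 455 to 688 in placebo and 487 to 995 in calcitriol arrays at the 3′ end, and from 41.5 to 62.9, 115 to 170 and 167 to 352 in the middle. Of 66 control probe sets, 3 were higher on all EAE arrays, where 0.786 would arise by chance, and the third, for Gapdh, has an exact 0 on a naive array. The probe set representing Actb also rose in EAE.

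In EAE placebo against naive, the monocyte, macrophage and microglia list shifted up and the neuron list down (camera adjusted p = 0.0783 and 0.0969 with an estimated correlation). A lower share of neural RNA would raise the markers of every other cell type alike, but the monocyte median exceeded the endothelium median by 0.535 log2 over the 26 and 21 genes above the floor on all naive arrays (permutation of genes, which takes them as independent, p = 0.00655) and by 0.48 to 0.70 log2 on the placebo arrays (-0.10 to 0.05 on the naive), which argues against it as the whole cause. With the beta-actin 5′ minus 3′ difference as a covariate, the mean neuron difference was -0.52 ± 0.17 log2 (SE, and -0.29 without it). The mean myeloid difference was then 1.64 ± 0.25 log2 (SE, and 1.06 without it). Within groups, arrays with a lower 5′ minus 3′ difference had neither higher myeloid nor lower neuron means (slopes 0.79 ± 0.28 and -0.30 ± 0.19, SE). The covariate did not overlap between naive and placebo arrays, so this fit cannot separate RNA integrity from EAE, and that cause stays open. Without naive replicate 2, which stood apart, the mean neuron difference was -0.29 ± 0.13 log2 (SE), against -0.29 ± 0.11 with it. The mean myeloid difference was 0.90 ± 0.19 log2 (SE) without it, so the size of neither mean rests on that array alone. The neuron difference was less certain without it, and naive replicate 2 had the highest neuron list median of the naive and placebo arrays. Entry or activation of myeloid cells with loss of neural transcripts may underlie the pattern, as an untested hypothesis.

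Calcitriol arrays lay further from naive than placebo arrays along the EAE change for 83 of 114 probe sets (27.2% moved back). With array weights, 44.3% of the larger set of probe sets then called moved back. If samples of 1 group already differ along the same axis, the difference may be between samples: the first within-group component of the EAE arrays correlated with the calcitriol minus placebo difference at 0.137 across probe sets, between the bounds set for and against this, so it stays open. That component was mostly calcitriol replicate 6 (score 46.5, against -21.3 and -25.2 on replicates 7 and 8 and -4.52 to 4.64 on the placebo arrays), and its correlation was 0.00846 in size with the EAE change itself and 0.276 with the calcitriol minus placebo difference over the EAE-changed probe sets. The array titled with another vitamin D compound, calcitriol replicate 6, is not the source, since without it 20% of the 75 probe sets then changed moved back, and 21.9% of the same 114. Calcitriol replicate 8 had the largest mean shift along the EAE change, 2.64 log2. Replicates 6 and 7, at 2.24 and 2.11 log2, lay within the placebo range of 1.95 to 2.29. A treatment effect at 6 h and a difference in disease severity between samples stay open and untested.

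The T cell list was not shifted in either EAE group against naive, whereas the myeloid list shifted up (camera adjusted p = 0.0783 in placebo and 0.0612 in calcitriol with an estimated correlation). Of the T cell genes, 11.5% (3 of 26) lay under 2 times the floor in both EAE groups. That is fewer than the majority expected if dim probe sets were the cause, but the floor is set and is no measured background, so this stays open. A small share of T cells within the cord may leave their genes unshifted, as an untested hypothesis.

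The 6 arrays of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. In placebo against naive the real split gave 114 changed probe sets and the highest other 0, and it gave 20 shifted lists with the highest other at 11 (1 split of 10 as large for each). In calcitriol against naive it gave 244 with the highest other at 10, and 18 lists with the highest other at 14 (1 split of 10 for each). In calcitriol against placebo it gave 0 changed probe sets in limma (314 at an unadjusted p under 0.05) with the highest other at 0 (10 splits of 10), and 5 lists with the highest other at 8, and 4 splits of 10 gave at least as many.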

How the results depend on the processing

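Exact zeros as missing was the alternative chosen after the data were seen. Of 41 named genes called in placebo against naive and 65 in calcitriol against naive, all kept their direction under 22 settings, and 9 and 28 kept their call under all of them. The kept direction says little. The groups of every called probe set did not overlap, so leaving out 1 array could hardly change a sign. Changes of filter, trend, threshold or groups fitted left the differences themselves as they were. The medians of the complement and endothelium lists, called higher in placebo against naive, turned negative in 2 and 1 settings. Changed probe sets in placebo against naive (114) were 639 with array weights (mostly on replicate 3 among the naive arrays), 61 with only the 2 groups fitted, and 20 to 176 with 1 array left out. In calcitriol against naive (244) they were 1014, 118, and 75 to 392. In calcitriol against placebo limma called 0 (314 unadjusted), and 0 to 1 with 1 array left out: without calcitriol replicate 6 Myl6, and without replicate 7 a probe set with no gene symbol, each at an exact 0 on both calcitriol arrays left. Shifted lists fell from 20, 5 and 18 to 0, 0 and 0 with an estimated correlation. Calcitriol against placebo had 0 with fry, 3 with array weights, 8 with exact zeros as missing, and 1 to 7 with 1 array left out, where the others had 18 to 21 and 16 to 19. The 27.2% of probe sets that moved back were 30.2% as deposited, 33.7% with the filter on the mean, 44.3% with array weights, 32.9% without trend, and 20% to 40.0% with 1 array left out. Each share is over the probe sets called in its own setting, so the sets differ. For all of these changes the cause was not tested. Unscaled, the median of all probe sets stood 0.11 log2 above naive in placebo, and Actb and the ribosomal protein median were higher in EAE under all scalings. The beta-actin 5′ minus 3′ difference of calcitriol from placebo changed sign, from 0.13 to -0.23 under quantile normalization and -0.02 without placebo replicate 1, and that from naive went from -0.62 to -0.88 under quantile normalization. No paired analysis was possible because the groups shared no replicate numbers. The floor, met by 6.12% to 11.3% of values per array, limits falls of dim genes.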

Other observations

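All genes below were chosen after their values were seen, and no explanation was tested. Outside the lists, S100a6, a calcium-binding protein, rose by 3.02 ± 0.30 log2 (SE, limma adjusted p = 0.00311) in placebo against naive and by 3.43 log2 in calcitriol against naive. The lysosomal proteases Ctsz (at least 2.81 log2, all naive arrays at the floor) and Ctsl (2.37 log2) and the tetraspanin Cd9 (2.10 log2) rose in placebo against naive as well. Ckb, which supplies ATP in brain, fell by 1.15 log2 in calcitriol against naive (limma adjusted p = 0.0306), where placebo against naive stood at -0.09 log2. Ptx3, a pentraxin of innate immunity, rose by 2.64 log2 in calcitriol against naive (limma adjusted p = 0.00312) and stood at 1.55 log2 in placebo against naive (limma adjusted p = 0.0503). The Ckb and Ptx3 differences between the EAE groups, -1.06 and 1.09 log2, did not pass (limma adjusted p = 1).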
